A study of Culex pipiens pallens with 6 samples.

How the data were processed

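Gene expression was measured by RNA sequencing in whole adult females of the mosquito Culex pipiens pallens. Per the labels' protocols, females were injected with 100 nL of a small interfering RNA against ILP1, insulin-like peptide 1, or of a negative control RNA (NC), and RNA was extracted 3 days after injection. Poly-A RNA was made into libraries with a TruSeq RNA kit, for which no strand marking is stated. There were 3 libraries per group, described as independent biological replicates. The labels also state that knockdown was checked by quantitative PCR, and those measurements were not analysed here.

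The authors deposited raw counts per gene for each library, in whole numbers, for 18968 gene models. The same table holds FPKM per library, made by the authors. Each deposited FPKM value equalled the count divided by gene length and by the library's total count in genes, with a largest relative difference of 5.09e-15, so it held nothing beyond the counts and was not tested. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.27 and inspected with FastQC 0.10.1, and TopHat2, HISAT2, HTSeq and DESeq were also named. The role of each aligner and the strand setting of the counting are not given in the sources used here, so overlapping or antisense genes cannot be told apart. Per the file headers, each library was also assembled with StringTie 2.1.4, guided by release 44 of the CpipJ2 annotation of Culex quinquefasciatus, and these assemblies carry a deposited TPM value per transcript. Gene identifiers and coordinates are those of CpipJ2, an assembly of a sister taxon of the mosquito sequenced, so reads that differ from that assembly can be lost and the loss can differ between genes. None of the identifiers matched the separate reference gene table (0 matches), and gene names come from the product descriptions in the deposited table, which gave a specific product for 11072 genes. Near-identical tandem copies can share reads under the authors' counting, and members of such clusters are reported as uncertain.

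The total count in genes lay between 7884313 and 9544975 reads per library. A count of 0 allows up to 3 reads, which is 0.312 to 0.374 CPM. Intervals and floors cover counting error only, because the reads carry no molecular identifiers. No 2 libraries were duplicates, since the lowest chi-square per degree of freedom over library pairs, taken over genes with 10 or more reads in the pair, was 13.3.

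Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust fitting, TMM normalisation, genes kept by filterByExpr), and 11772 genes were tested. Values are given as CPM, counts scaled to the normalised library size. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. ILP1 had too few reads to pass the filter. Its main value is therefore the difference of mean log2 CPM (prior count 2), with a two-sided exact permutation test, beside the edgeR test without the filter and the ratio of summed reads with an exact 95% Poisson interval. Gene lists were defined by product names before the data were examined, 30 by function and 9 as markers of tissues or cell types, and 38 had at least 5 tested genes. Yolk uptake and lipophorin, with 4 tested genes, was not tested. Lists were tested with limma 3.58.1 (camera on log2 CPM, preset correlation 0.01), with adjustment over all 38 lists. Camera with a correlation estimated for each list and the rotation test fry were the alternatives.

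The genes named were set by a rule fixed before the data were examined. It takes every gene annotated as an insulin-like peptide and the 12 largest rises and falls past the threshold with a named product, a mean of at least 1 CPM and groups that do not overlap. Where no gene passes, it takes the 4 with the smallest p in each direction. It also takes, per list, up to 4 members with the smallest p. Genes outside the rule are marked where they are named.

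Both groups carry replicate numbers 1 to 3. The deviations of same-numbered libraries from their group means correlated across genes with 0.22 for number 1, 0.60 for number 2 and 0.27 for number 3. All were above 0.1, so the numbers were taken to pair the libraries, although the labels do not say what a number shares and 4 of the 6 libraries correlated best with their own number. NC replicate 1 with siILP1 replicate 3 (0.47) and NC replicate 3 with siILP1 replicate 1 (0.15) also lay above 0.1. This check therefore cannot show that the numbers mark pairs, and every result by pair rests on that assumption. The main edgeR and camera tests, camera with an estimated correlation, fry and the exact permutation tests leave these pairs out of account. The pairs enter only in the fits with a replicate block and where pairs are named.

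Alternatives were DESeq2 size factors in edgeR, no low-count filter, a filter of 1 CPM in 3 libraries, a replicate block, each library left out in turn, DESeq2 1.42.0, limma-voom, a minimum absolute log2 fold change of 1, and limma-trend on log2(TPM + 1) or log2(TPM + 0.1) of 5228 genes with a StringTie locus of their own and at least 1 TPM in 3 libraries. The DESeq2 fit with a replicate block, the joint removal of NC replicate 1 and siILP1 replicate 2, the removal of both replicates of the same number, a covariate made from marker lists and the test of gene ontology terms were added after the data were examined. The code was tested on 5 simulated data sets of the 11772 genes, with means and dispersions taken from the 6 libraries. At a 4-fold change edgeR recovered 300 of 500 changed genes and DESeq2 392 of 500. At a 2-fold change they recovered 20 and 85 of 500. Over all 5 sets edgeR made 28 false calls and DESeq2 144, and camera called all 5 shifted lists and 0 of 195 unshifted lists. Each gene was drawn independently, so false list calls from correlated members could not arise, and the 0 of 195 says nothing about them. For the blocked fits, 5 further sets were simulated with the replicate effect of the 6 libraries and no group effect, in which edgeR made 26 and DESeq2 39 calls in total. These sets also drew each gene independently.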

Results

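RNA was sequenced from whole adult female Culex pipiens pallens in 6 libraries, 3 from females injected with negative control RNA (NC) and 3 labelled siILP1, from females injected with small interfering RNA against insulin-like peptide 1. The series asks how this insulin-like peptide, which is studied for its part in diapause and in the arrest of the ovary, affects gene expression. Library totals were 9362103, 9544975 and 8534057 reads in genes for NC replicates 1, 2 and 3, and 8898694, 7884313 and 8189907 for replicates 1, 2 and 3 labelled siILP1.

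The targeted gene was not lower in the libraries labelled siILP1. Insulin-like peptide 1 (CPIJ018051, CpipJ2 supercontig 3.1083, 45953 to 47761, minus strand), a secreted hormone of the insulin family, had 1, 4 and 3 reads in NC replicates 1, 2 and 3 and 9, 7 and 9 reads in replicates 1, 2 and 3 labelled siILP1. Its mean was 0.291 ± 0.157 CPM in NC (SD, n = 3) and 0.988 ± 0.0991 CPM in the libraries labelled siILP1 (SD, n = 3). The summed reads, 8 against 25, gave a ratio of 3.35 with an exact 95% Poisson interval of 1.47 to 8.59. The difference of mean log2 CPM was 1.27, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow with the pairs left out of account. Without the low-count filter, edgeR gave a log2 fold change of 1.71 (SE 0.75) with an adjusted p of 0.889. These counts go against the label, and every direction drawn below is between libraries labelled siILP1 and NC.

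The other annotated insulin-like peptides did not pass the test either. Insulin-like peptide 5 (CPIJ001698, supercontig 3.19, 1147555 to 1151725) stood at 2.33 ± 1.10 CPM in NC and 2.19 ± 1.14 CPM in the libraries labelled siILP1 (SD, n = 3 each). Insulin-like peptide 6 (CPIJ003329, supercontig 3.47, 1150769 to 1154835) stood at 30.8 ± 20.7 and 38.2 ± 10.8 CPM. Their log2 fold changes were -0.08 (95% interval -1.45 to 1.29) and 0.31 (95% interval -0.86 to 1.49), and each sign turned in edgeR when NC replicate 1 was left out (0.31 and -0.09). The 2 gene models before insulin-like peptide 1 on its supercontig, chosen after their values were seen, are uncharacterized. CPIJ018049 had a log2 fold change of 0.26 (SE 0.40) and CPIJ018050, on the same strand and ending before the insulin-like peptide 1 model begins, had -0.18 (SE 0.52).

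**Figure D1:**
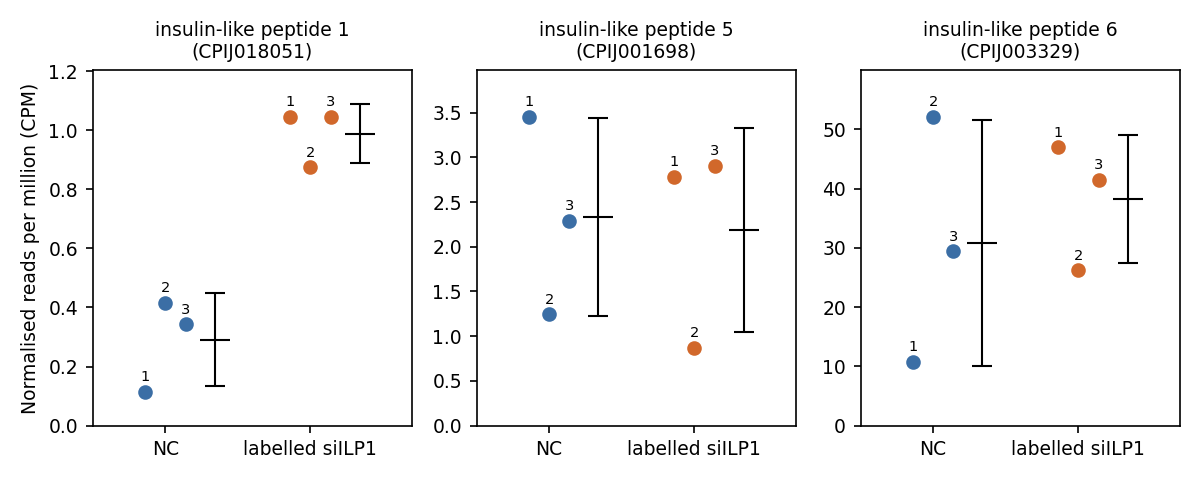
Normalised expression (CPM) of the 3 annotated insulin-like peptide genes in each library; points are libraries with their replicate number, and the bar beside them is the mean with its SD. For insulin-like peptide 1 all 3 libraries labelled siILP1 lie above all 3 NC libraries, with means of 0.988 and 0.291 CPM.

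At the level of single genes, no transcript passed the test. The leading named genes that were higher in all 3 libraries labelled siILP1 were DNA polymerase theta (CPIJ020174, supercontig 3.2518, 6007 to 10704), an enzyme of DNA break repair, zinc finger protein 73 (CPIJ011640), the nuclear transport GTPase ran (CPIJ019028) and mitogen-activated protein kinase kinase kinase 7 (CPIJ000187). DNA polymerase theta stood at 24.7 ± 6.20 CPM in NC and 61.2 ± 14.7 CPM in the libraries labelled siILP1, a log2 fold change of 1.31 (SE 0.27), and ran at 26.5 ± 10.3 and 54.2 ± 5.19 CPM (SD, n = 3 each). The leading named genes that were lower in all 3 were an ABC transporter (CPIJ001160), a short-chain dehydrogenase (CPIJ016763), a cytochrome P450 (CPIJ009471) and odorant binding protein OBP29 (CPIJ016966). The short-chain dehydrogenase (supercontig 3.848, 186288 to 188412) stood at 43.0 ± 19.9 CPM in NC and 11.3 ± 6.07 CPM in the libraries labelled siILP1, and OBP29 at 9.94 ± 2.81 and 3.35 ± 1.19 CPM (SD, n = 3 each). These genes are given as values, since the lowest adjusted p of edgeR's quasi-likelihood test over all genes was 0.908. DESeq2 with the replicate block, added after the data were examined, called 5 of the 8: DNA polymerase theta (adjusted p 0.00157), zinc finger protein 73 (adjusted p 0.0482), ran (adjusted p 0.0128), mitogen-activated protein kinase kinase kinase 7 (adjusted p 0.000131) and the short-chain dehydrogenase (adjusted p 0.00157). For these 5, adjusted p was 0.373 to 0.384 in edgeR with the block and 0.293 to 0.986 in DESeq2 without it. The 8 were picked by their edgeR p in the same counts, so these calls are not independent support.

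By edgeR 0 of 11772 genes passed an adjusted p of 0.05, and 365 had an unadjusted p under 0.05, 144 higher and 221 lower, where 589 are expected by chance. Limma-voom also called 0 genes. DESeq2 called 1, the uncharacterized CPIJ015243, which was lower in the libraries labelled siILP1 (log2 fold change -3.50, SE 0.72, adjusted p 0.0189) with 406, 28 and 255 reads in NC replicates 1, 2 and 3 against 19, 21 and 18. EdgeR called the same gene when NC replicate 2 was left out (adjusted p 0.0477). In 911 genes (7.74%), 492 higher and 419 lower, the groups did not overlap, where chance gives 10% for 3 against 3. These chance values treat the 6 libraries as exchangeable and leave the pairing by number out of account. With the replicate number as a block, edgeR again called 0 genes, but 1435 had an unadjusted p under 0.05, more than the 589 expected by chance. DESeq2 with the block called 57, 19 higher and 38 lower, a fit added after the data were examined. CPIJ015243 was not among these 57 (adjusted p 0.1985 in DESeq2 with the block).

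The groups overlapped along the main axis of variation, while within each numbered pair the library labelled siILP1 lay higher on it. The first principal component of log2 CPM held 57.4% of the variance and placed NC replicates 1, 2 and 3 at -55.1, 35.9 and -35.0 and the libraries labelled siILP1 at 2.101, 73.4 and -21.3. Correlations of log2 CPM averaged 0.933 between libraries of the same group and 0.934 between groups.

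**Figure D2:**
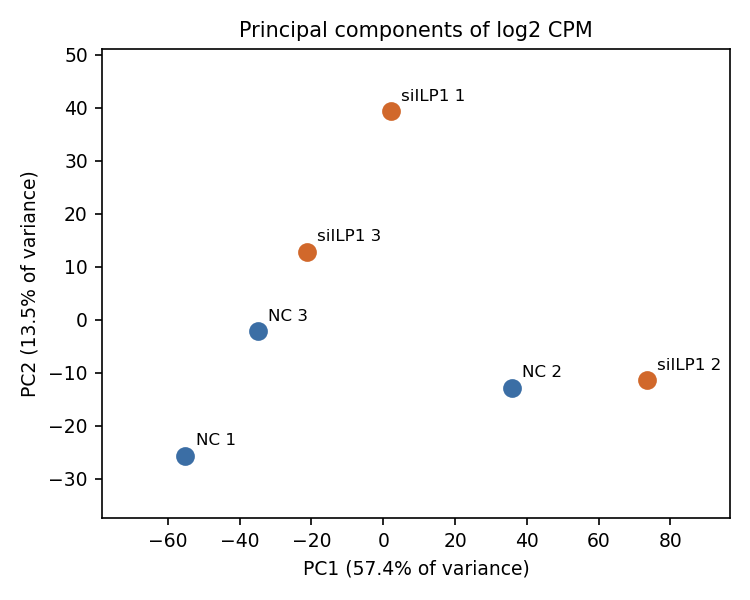
The 6 libraries on the first and the second principal component of log2 CPM, which hold 57.4% and 13.5% of the variance; blue points are NC and orange points the libraries labelled siILP1, with replicate numbers. Both replicates numbered 2 lie at the right, at 35.9 and 73.4, apart from the other libraries.

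Lists for oxidative phosphorylation, sugar metabolism and lipid synthesis were each called lower in the libraries labelled siILP1 with the preset correlation. The NC and siILP1 libraries overlapped in the mean expression of each list, with NC replicate 2 below siILP1 replicate 3. Lipid breakdown (adjusted p 0.273 in the camera test) and sugar digestion (adjusted p 0.259) were not called. Of 61 tested genes for oxidative phosphorylation, the mitochondrial respiratory chain and ATP synthase, 56 had lower and 5 higher means (median log2 fold change -0.44), and the list fell in the camera test (adjusted p 2.1e-09; adjusted p = 0.882 with an estimated correlation). The ATP synthase D chain (CPIJ011691) stood at 534.6 ± 140.8 CPM in NC and 344.1 ± 40.1 CPM in the libraries labelled siILP1, succinate dehydrogenase (CPIJ017679) at 32.4 ± 11.2 and 19.1 ± 2.70 CPM, and the 14 kDa protein of the cytochrome c reductase complex (CPIJ019847) at 18.8 ± 8.10 and 6.79 ± 1.80 CPM (SD, n = 3 each). Sugar, glycogen and trehalose metabolism fell with 31 of 36 genes lower (median -0.29, adjusted p 0.00473; adjusted p = 0.882 with an estimated correlation), and its leading members were 3 tandem genes for phosphoenolpyruvate carboxykinase, which commits carbon to the making of glucose. Their log2 fold changes were -4.37 (SE 1.39, CPIJ010516), -2.40 (SE 0.82, CPIJ010515) and -1.79 (SE 0.69, CPIJ010518), which are uncertain because the copies can share reads and NC replicate 1 alone held 689, 867 and 665 of their reads. Lipid synthesis and storage fell with 51 of 69 genes lower (median -0.36, adjusted p 0.000726; adjusted p = 0.882 with an estimated correlation). Fatty acid synthase (CPIJ005595, supercontig 3.95, 149817 to 163261) stood at 1045 ± 343 CPM in NC and 631 ± 183 CPM in the libraries labelled siILP1, and a sterol desaturase (CPIJ017305) at 18.1 ± 7.71 and 6.92 ± 2.42 CPM (SD, n = 3 each). Members of the lipid list include 30 fatty acyl-CoA reductases and elongases, many of which make waxes and long-chain lipids and do not store fat. In each of these lists 0 members passed the edgeR test over all genes and 0 adjusted over the list alone. DESeq2 with the replicate block called 1 member of each, lower, among them CPIJ010518 (adjusted p 0.0372) and CPIJ017305 (adjusted p 0.0390). Without NC replicate 1 the median of oxidative phosphorylation was -0.19 (adjusted p 0.00216) and that of lipid synthesis -0.18 (adjusted p 0.0222), and the sugar call was lost (-0.15, adjusted p 0.211). Without siILP1 replicate 2 the sugar (-0.13, adjusted p 0.218) and lipid (-0.19, adjusted p 0.121) calls were lost. Without both libraries all 3 calls were lost, with medians of -0.075 for oxidative phosphorylation, -0.056 for lipid synthesis and -0.047 for sugar metabolism, where the direction of the test turned. These libraries lie at opposite ends of the first principal component (-55.1 and 73.4), and the fit was chosen after the data were examined. Their joint removal had to shrink the group difference along it, here and in the lists below, so this fit decides nothing. The sugar median was -0.43 without NC replicate 2, and the sugar and lipid medians were -0.46 and -0.62 without siILP1 replicate 3. Without both replicates numbered 1 the sugar (-0.20, adjusted p 0.286) and lipid (-0.15, adjusted p 0.0528) calls were lost, and all 3 held without both numbered 2 or both numbered 3.

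Detoxification, cuticle and immune genes were also called lower as groups, but immune genes were not lower in every pair. In mean expression of these lists, and of neuropeptides and their receptors, NC replicate 2 lay below siILP1 replicate 3. The NC and siILP1 libraries thus overlapped in each. Within numbered pairs 1, 2 and 3 the mean log2 CPM shifted by -0.40, -0.38 and -0.13 for detoxification. The shifts were -1.385, -0.715 and -0.077 for cuticle and -0.13, -0.82 and 0.14 for immune genes. The list of cytochrome P450s, glutathione S-transferases, esterases and related transporters fell with 146 of 197 genes lower (median -0.29, adjusted p 1.7e-05; adjusted p = 0.882 with an estimated correlation). It holds 106 cytochrome P450s, among them P450 12F13 (CPIJ010227) at 52.4 ± 40.4 CPM in NC and 12.9 ± 1.67 CPM in the libraries labelled siILP1 (SD, n = 3 each). NC replicates 1, 2 and 3 had 96.5, 17.0 and 43.7 CPM of that gene, so replicate 1 set much of the NC mean. All 15 tested cuticle protein genes had lower means (median -0.68, adjusted p 3.9e-05; adjusted p = 0.882 with an estimated correlation), and 10 of them are described as larval or pupal cuticle proteins although the samples were adults. Immune response genes fell with 75 of 110 lower (median -0.20, adjusted p 0.00384; adjusted p = 0.904 with an estimated correlation), led by leucine-rich immune proteins such as CPIJ017601 at 155.6 ± 36.03 and 108.3 ± 19.7 CPM. The mean deviation of immune genes from their averages was 0.30, -0.14 and 0.23 log2 CPM in NC replicates 1, 2 and 3. It was 0.18, -0.95 and 0.37 in the libraries labelled siILP1, so replicate 2 carried the fall and replicate 3 was the highest of all libraries. Neuropeptides and their receptors fell with 7 of 9 lower (median -0.66, adjusted p 0.01004; adjusted p = 0.882 with an estimated correlation), among them short neuropeptide F (CPIJ009048), a feeding-related peptide, at 12.5 ± 6.17 and 5.48 ± 3.06 CPM (SD, n = 3 each). In edgeR 0 members of each list passed over all genes and 0 adjusted over the list alone. DESeq2 with the replicate block called 1 detoxification gene, P450 12F13 (adjusted p 0.00157), and 1 cuticle gene, CPIJ013782 (adjusted p 2.5e-05), both lower. It called 0 immune or neuropeptide genes. The cuticle call held without any single library, with medians of -0.39 without NC replicate 1 and -1.02 without siILP1 replicate 3. It was lost without NC replicate 1 and siILP1 replicate 2 together (-0.19, adjusted p 0.696). The detoxification median was -0.13 without NC replicate 1, and the call was lost without siILP1 replicate 2 (-0.16, adjusted p 0.1399) and without both libraries (-0.055). The immune call was lost without NC replicate 1 (-0.080, adjusted p 0.0653) and turned direction without siILP1 replicate 2 (0.022, adjusted p 0.193). Without both libraries immune genes were called higher (0.11, adjusted p 0.0170). The immune median was -0.34 without NC replicate 2 and -0.46 without siILP1 replicate 3. The neuropeptide call was lost without the low-count filter (-0.23, adjusted p 0.172), without NC replicate 1 (-0.20), NC replicate 3 (-0.54) or siILP1 replicate 2 (-0.38), and without NC replicate 1 and siILP1 replicate 2 together (-0.019). Without both replicates numbered 1 the cuticle (-0.30, adjusted p 0.05001) and neuropeptide (-0.49, adjusted p 0.0555) calls were lost. The immune call was lost without both numbered 2 (-0.16, adjusted p 0.791), and the neuropeptide call without both numbered 3 (-0.67, adjusted p 0.0686).

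Genes of DNA replication and ribosome making were called higher as groups with the preset correlation. The NC and siILP1 libraries overlapped in the mean expression of both lists, with siILP1 replicate 3 below NC replicate 2. DNA replication and cell cycle rose with 47 of 53 genes higher (median 0.42, adjusted p 6.7e-09; adjusted p = 0.882 with an estimated correlation). The large subunit of ribonucleoside-diphosphate reductase (CPIJ005992), which makes deoxyribonucleotides, stood at 91.0 ± 7.63 CPM in NC and 178 ± 70.9 CPM in the libraries labelled siILP1, and its small chain (CPIJ002337) at 67.7 ± 9.61 and 128.5 ± 62.7 CPM (SD, n = 3 each). The licensing factor mcm5 (CPIJ008678), part of the replicative helicase, stood at 21.3 ± 3.61 and 46.6 ± 27.1 CPM, and Cdt1 (CPIJ009958), which loads that helicase, at 2.42 ± 0.593 and 10.1 ± 8.69 CPM. Much of both rises lay in replicate 2 labelled siILP1, with 32.4, 77.9 and 29.5 CPM for mcm5 and 6.27, 20.1 and 4.07 CPM for Cdt1 in replicates 1, 2 and 3. Ribosome biogenesis rose with 35 of 42 genes higher (median 0.16, adjusted p 0.00103; adjusted p = 0.882 with an estimated correlation), among them nucleolar protein 6 (CPIJ008905) at 68.4 ± 3.25 and 86.0 ± 7.86 CPM. In both lists 0 members passed over all genes in edgeR, 0 adjusted over the list alone and 0 in DESeq2 with the replicate block. The replication call held without any single library, with a median of 0.28 without siILP1 replicate 2, and without that library and NC replicate 1 together (0.20, adjusted p 0.0170). The ribosome biogenesis call was lost without NC replicate 1 (0.075, adjusted p 0.142), siILP1 replicate 2 (0.12, adjusted p 0.1399) or both (-0.047), and its median was 0.37 without NC replicate 2 and 0.26 without siILP1 replicate 3. Without both replicates numbered 1 the ribosome biogenesis call was lost (0.040, adjusted p 0.186).

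Markers of 4 tissues were called lower, although the groups overlapped in the mean expression of each of these lists. The two-sided exact permutation p of mean log2 CPM was 0.3 for eye and neuron, 0.4 for muscle, 0.7 for salivary gland and 0.3 for Malpighian tubule markers. In numbered pair 3, salivary gland (0.38) and Malpighian tubule markers (0.024) were higher in the library labelled siILP1. Eye and neuron markers fell with 27 of 30 lower (median -0.46, adjusted p 0.00103; adjusted p = 0.882 with an estimated correlation), including a long wavelength opsin (CPIJ020021), a light receptor of the eye, at 17.1 ± 7.29 CPM in NC and 4.72 ± 4.50 CPM in the libraries labelled siILP1. Muscle markers fell with 24 of 30 lower (median -0.57, adjusted p 0.00349; adjusted p = 0.882 with an estimated correlation), including troponin C (CPIJ012250), a calcium sensor of muscle, at 432.1 ± 134.3 and 216.3 ± 113.2 CPM. Salivary gland markers fell with 34 of 51 lower (median -0.31, adjusted p 0.00384; adjusted p = 0.889 with an estimated correlation), and 10 of these genes are also in the immune list and 4 are tRNA adenosine deaminases, matched by name only. Malpighian tubule markers fell with 21 of 25 lower (median -0.19, adjusted p 0.00699; adjusted p = 0.882 with an estimated correlation), and 13 of them are subunits of the vacuolar ATPase, a proton pump of many tissues. In edgeR 0 members of each list passed over all genes and 0 adjusted over the list alone. DESeq2 with the replicate block called 3 eye and neuron markers, among them CPIJ020021 (adjusted p 0.0169), and 2 muscle markers, among them CPIJ012250 (adjusted p 0.00163), all lower. It called 0 salivary gland or Malpighian tubule markers. Without siILP1 replicate 2 all 4 calls were lost (-0.31 for eye and neuron, -0.26 for muscle, -0.12 for salivary gland, where the direction of the test turned, and -0.044 for Malpighian tubule markers). Without NC replicate 1 the muscle (-0.24), salivary gland (-0.068) and Malpighian tubule (-0.12) calls were lost. Without both libraries the 4 medians were -0.026, 0.0042, 0.17 and 0.025, with none called. Since that removal takes away the opposite ends of the first principal component and leaves their partners unmatched, smaller shifts were built in. The eye and neuron median was -0.30 without NC replicate 3 and the Malpighian tubule median -0.32 without NC replicate 2. Without siILP1 replicate 3 the muscle, salivary gland and Malpighian tubule medians were -1.01, -0.59 and -0.37. Without both replicates numbered 1 the muscle (-0.15, adjusted p 0.351) and Malpighian tubule (-0.11, adjusted p 0.0764) calls were lost. Without both numbered 2 the Malpighian tubule call (-0.17, adjusted p 0.221) was lost, and the salivary gland test turned direction (-0.19, adjusted p 0.738). Ovary and germline markers, 8 of 17 of them piwi genes, had 12 higher and 5 lower and were not called (median 0.18, adjusted p 0.107), although the call was made without NC replicate 2 (adjusted p 0.0135) or NC replicate 3 (adjusted p 0.0372). Fat body (median -0.18, adjusted p 0.840), midgut (-0.12, 0.665), haemocyte (-0.03, 0.947) and testis and sperm markers (-0.05, 0.788) were not called.

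**Figure D3:**
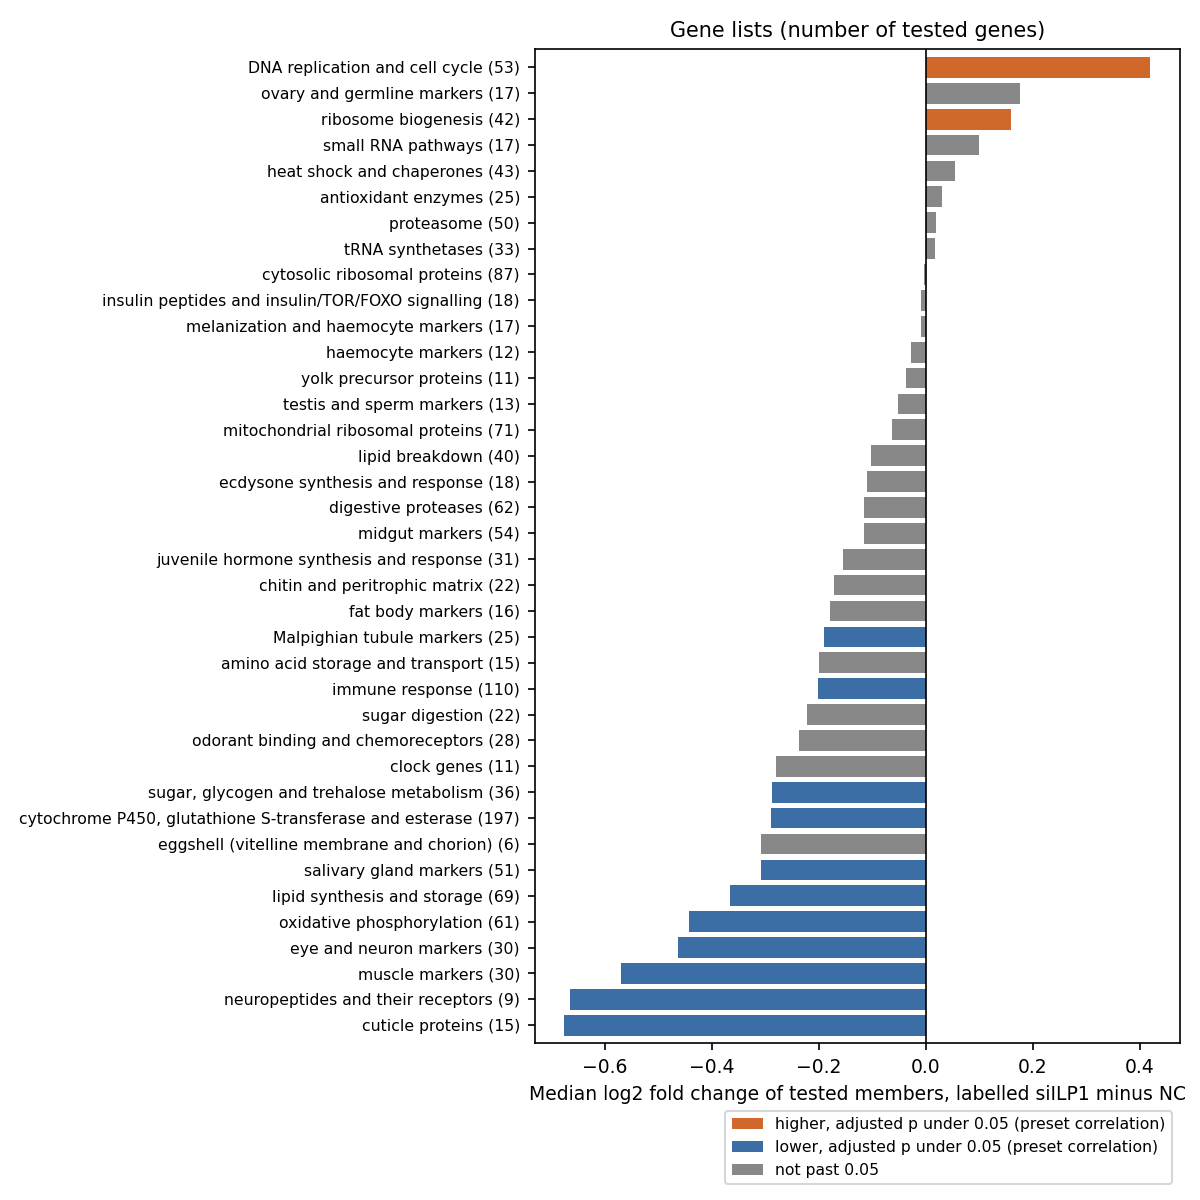
Median log2 fold change of the tested members of each of the 38 gene lists, labelled siILP1 minus NC, with the number of tested genes in brackets; coloured bars passed an adjusted p of 0.05 with the preset correlation. The 11 lower lists run from cuticle proteins (-0.68) to Malpighian tubule markers (-0.19), and DNA replication and cell cycle (0.42) and ribosome biogenesis (0.16) are higher; 0 lists passed with an estimated correlation.

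Insulin signalling and reproduction lists were not called. Insulin peptides with insulin, TOR and FOXO signalling genes had 7 of 18 higher and 11 lower (median -0.01, adjusted p 0.947), including a phosphatidylinositol 3-kinase regulatory subunit (CPIJ011236) at 23.6 ± 5.09 CPM in NC and 30.2 ± 5.63 CPM in the libraries labelled siILP1 (SD, n = 3 each). Yolk precursor proteins had 5 of 11 higher (median -0.04, adjusted p 0.738), and a vitellogenic carboxypeptidase (CPIJ008608) stood at 229.8 ± 69.6 and 295.1 ± 79.0 CPM. Eggshell genes had 2 of 6 higher (median -0.31, adjusted p 0.947; 0.47 without NC replicate 2 and 0.060 with the replicate block), with chorion peroxidase CPIJ007711 at 219 ± 149 and 391 ± 184 CPM and chorion peroxidase CPIJ001764 at 33.6 ± 20.7 and 17.9 ± 7.80 CPM. Juvenile hormone synthesis and response had 12 of 31 higher (median -0.15, adjusted p 0.0930) and was called lower only without siILP1 replicate 3 (adjusted p 0.0439). Ecdysone synthesis and response had 8 of 18 higher (median -0.11, adjusted p 0.259), and ecdysone-induced protein 74EF (CPIJ003069), an early gene of the moulting hormone response, had a log2 fold change of -1.44 (SE 0.46).

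The remaining lists were not called either. Odorant binding proteins and chemoreceptors had 22 of 28 lower (median -0.24, adjusted p 0.0930) and were called lower without NC replicate 2 (adjusted p 0.0120), siILP1 replicate 3 (adjusted p 0.0140) or both replicates numbered 2 (adjusted p 0.0191). Sugar digestion (median -0.22, adjusted p 0.259) was called lower without NC replicate 2 (adjusted p 0.0344), and mitochondrial ribosomal proteins (-0.06, 0.415) without NC replicate 3 (adjusted p 0.0360). Without NC replicate 1 and siILP1 replicate 2 together, sugar digestion was called higher (median 0.36, adjusted p 0.0375) and testis and sperm markers lower (median -0.32, adjusted p 0.0375). Medians and adjusted p were -0.10 and 0.273 for lipid breakdown, -0.12 and 0.633 for digestive proteases, 0.02 and 0.665 for tRNA synthetases, -0.28 and 0.710 for clock genes and 0.10 and 0.710 for small RNA pathways. They were -0.17 and 0.723 for chitin and peritrophic matrix, -0.20 and 0.788 for amino acid storage and transport, 0.02 and 0.931 for the proteasome, -0.01 and 0.947 for melanization genes and 0.03 and 0.947 for antioxidant enzymes. Cytosolic ribosomal proteins had 43 of 87 higher (median -0.003, adjusted p 0.710) and were called higher without both replicates numbered 2 (0.077, adjusted p 0.0355). Among the lists not called, only odorant binding, ecdysone, lipid breakdown, mitochondrial ribosomal protein and clock genes kept the sign of their median in every fit other than the one with the ovary covariate. The median and the test differed in sign for cytosolic ribosomal proteins, amino acid storage and transport, melanization genes and heat shock genes. The median and mean differed in sign for cytosolic ribosomal proteins, heat shock genes, yolk precursors, fat body markers and antioxidant enzymes.

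Heat shock genes and chaperones as a list had 22 of 43 higher (median 0.05, mean -0.44, adjusted p 0.788). Of its 4 leading members, 3 were lower in all 3 libraries labelled siILP1 than in any NC library. The groups overlapped for the fourth, heat shock protein 26 (CPIJ005640), with 793, 202 and 453 reads in NC replicates 1, 2 and 3 and 104, 124 and 275 in the libraries labelled siILP1 (log2 fold change -1.46, SE 0.56). Heat shock protein 70 B2 (CPIJ011081, supercontig 3.316, 27117 to 29033), a stress-induced chaperone, had 186, 29 and 1713 reads in NC replicates 1, 2 and 3 and 13, 17 and 21 in the libraries labelled siILP1. Its neighbouring copy CPIJ011082 had 89, 20 and 972 against 4, 10 and 8 reads, and the copies can share reads. Heat shock protein 27 (CPIJ005642, supercontig 3.99, 255738 to 256304) had 28, 14 and 900 against 6, 2 and 6 reads. Their log2 fold changes were -5.17 (SE 1.37), -5.53 (SE 1.44) and -5.98 (SE 1.72), and without NC replicate 3 they were -2.59, -2.80 and -2.06. None passed edgeR's test (adjusted p 0.908).

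**Figure D4:**
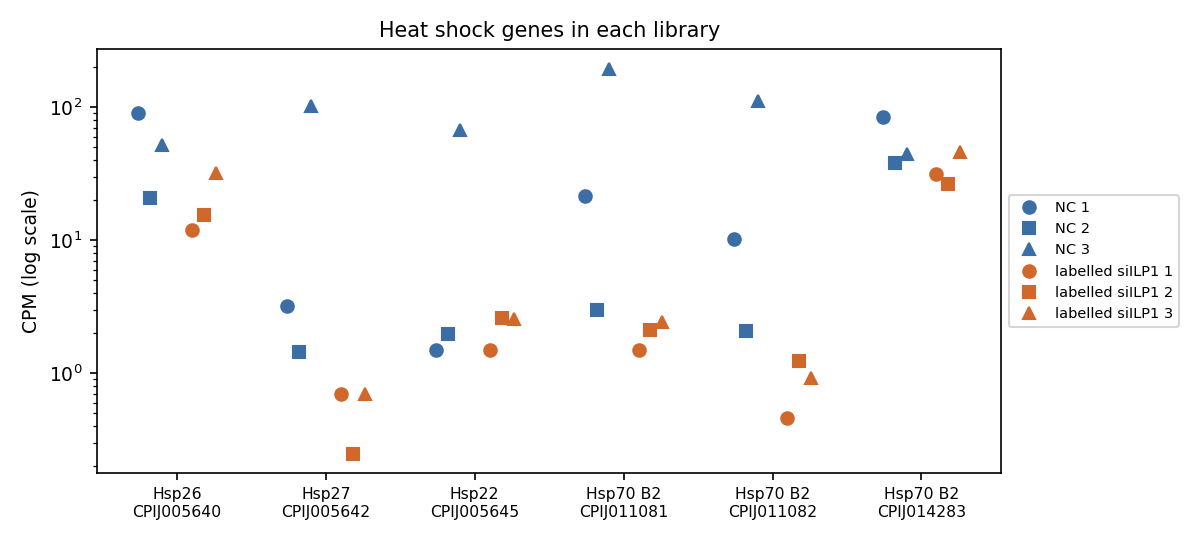
CPM on a log scale of 6 heat shock genes in each library; blue is NC, orange the libraries labelled siILP1, and the symbol gives the replicate number. NC replicate 3 is highest for 4 of the genes, at 196.1 CPM for CPIJ011081, where the libraries labelled siILP1 lie between 1.509 and 2.442 CPM.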

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

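The DESeq2 fit with a replicate block and the fits without NC replicate 1 and siILP1 replicate 2 together, without both replicates of the same number, with the ovary marker covariate and with gene ontology terms were chosen after the data were examined. The count of changed genes was 0 in edgeR with DESeq2 size factors, without a filter, with the CPM filter, with the fold minimum and with the replicate block, in limma-voom and in both TPM tests. It was 1 in DESeq2, 57 in DESeq2 with a replicate block, 0 to 1 with a single library left out, and 0 without both replicates of any number. With the block DESeq2 no longer called CPIJ015243 (adjusted p 0.1985), and calls of some gene ontology terms changed, as given with the other observations. The block changed no other call in edgeR or among the 38 lists, where it called the same 13. Why DESeq2 with the block called more was not tested. The ILP1 difference kept its sign under every alternative run, from 1.00 to 1.44 with a library left out, 1.75 with the replicate block, 1.75 in DESeq2 and 0.37 on log2(TPM + 1). In TPM the groups overlapped, with 0, 0.0555 and 0.263 in NC replicates 1, 2 and 3 (two-sided exact permutation p 0.2). Replicates 1, 2 and 3 labelled siILP1 had 0.541, 0.116 and 0.662. The assembly of NC replicate 1 lists no reference transcript of the gene.

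The count of called lists, 13 in the main test, was 13 with DESeq2 size factors and the CPM filter, 12 without a filter (neuropeptides lost), 3 to 16 with a library left out, 4 without NC replicate 1 and siILP1 replicate 2 together, of which only DNA replication and cell cycle was a main call in the same direction, 6 without both replicates numbered 1, 12 without both numbered 2 or both numbered 3, 2 with the ovary marker covariate, 0 with an estimated correlation (lowest adjusted p 0.882) and 0 in fry (lowest adjusted p 0.829). The estimated correlations of the called lists were 0.160 to 0.685, against the preset 0.01. With an estimated correlation camera also tests on fewer degrees of freedom, limited by the 6 libraries. The loss of all calls therefore cannot be put down to the correlation alone. Why this and the other choices lost calls was not tested, but the joint removal took away the libraries at opposite ends of the first principal component. Of the main calls, 6 held without NC replicate 1, 3 without siILP1 replicate 2, 6 without both replicates numbered 1, 10 without both numbered 2 and 12 without both numbered 3. The test turned direction without siILP1 replicate 2 for salivary gland markers (median -0.12) and immune response (0.022), and without both replicates numbered 2 for salivary gland markers (-0.19). With a library left out their medians ran from -0.59 to -0.068 and from -0.46 to 0.022. Without NC replicate 1 and siILP1 replicate 2 together it turned for muscle (0.0042), salivary gland (0.17) and Malpighian tubule markers (0.025), sugar, glycogen and trehalose metabolism (-0.047) and immune response (0.11, adjusted p 0.0170). Depth limits ILP1, with 1 to 9 reads per library.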

Other observations

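The DESeq2 fit with a replicate block and the gene ontology test were chosen after the data were examined, as were the tests of the heat shock and ILP1 patterns, the comparison of covariates and the fits without both replicates of a number. The 57 genes of that DESeq2 fit, chosen after their values were seen, had the same sign in edgeR without a block, and 23 are uncharacterized. Among the 38 lower in the libraries labelled siILP1 were 3 opsins and 2 troponin C genes, a myosin heavy chain (CPIJ000849, log2 fold change -0.91, SE 0.25), a pupal cuticle protein (CPIJ013782, -1.58, SE 0.27) and cytochrome c oxidase subunit VIb (CPIJ012223, -1.17, SE 0.30). Among the 19 higher were DNA polymerase theta (CPIJ020174, 1.31, SE 0.27), phosphatidylcholine-sterol acyltransferase (CPIJ010978, 1.27, SE 0.24), deoxycytidylate deaminase (CPIJ004863, 1.56, SE 0.38) and importin-11 (CPIJ007634, 0.79, SE 0.20). The other splits that part all 3 pairs gave 21, 8 and 2 genes in the same fit, and 5 simulated sets with the replicate effect and no group effect gave at most 13. With so few splits a first rank decides nothing. The simulated sets drew each gene independently, so they cannot show how far the number of calls spreads when genes are correlated.

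Of 149 gene ontology terms for biological processes with 10 to 500 tested genes, 18 were higher and 14 lower in the libraries labelled siILP1 with the preset correlation, and 0 passed with an estimated correlation (lowest adjusted p 0.795). DNA replication initiation had all 14 genes higher (median log2 fold change 0.62, adjusted p 2.8e-06; adjusted p = 0.795 with an estimated correlation) and DNA repair 66 of 81 (0.30, adjusted p 8.8e-05; adjusted p = 0.795 with an estimated correlation). Chitin metabolic process had 9 of 48 higher (-0.43, adjusted p 1.5e-05), visual perception 0 of 12 (-0.52, adjusted p 0.0140) and glycolytic process 0 of 15 (-0.27, adjusted p 0.0292), each with an adjusted p = 0.795 with an estimated correlation. Of the terms closest to the ribosome biogenesis list, rRNA processing was called, with 22 of 25 higher (0.18, adjusted p 0.0292; adjusted p = 0.795 with an estimated correlation), and ribosome biogenesis was not, with 18 of 27 higher (0.16, adjusted p 0.0712). With the replicate block, histone acetylation was no longer called (adjusted p 0.0508), and RNA processing (adjusted p 0.0466), ion transmembrane transport (adjusted p 0.00970), proteolysis (adjusted p 0.0416) and nucleic acid phosphodiester bond hydrolysis (adjusted p 0.0466) were. Loci without a reference gene held 21.8% to 27.0% of the assembled TPM in NC and 23.0% to 25.4% in the libraries labelled siILP1.

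ILP1 reads were not lower in the libraries labelled siILP1. A single exchange of an NC and a siILP1 library stays open: the lowest ratio over the 9 exchanges was 1.13, but its exact 95% Poisson interval, 0.538 to 2.39, includes a fall. Exchanges of more libraries, or of the whole groups, were not tested and stay open. That the RNA acted on another annotated insulin-like gene stays open: the lowest log2 fold change among the other insulin-like genes and the 2 neighbours was -0.181, but its interval reaches below -1. Reads of Culex pipiens pallens counted on gene models of a sister taxon, an effect on protein or a knockdown that had faded by 3 days were not tested.

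The list shifts may follow how much RNA each tissue gave, and ovary markers were higher in each numbered pair of libraries (5.69 to 6.26, 6.49 to 6.58 and 6.11 to 6.20 log2 CPM; means 6.10 ± 0.404 and 6.35 ± 0.201, SD, n = 3 each, two-sided exact permutation p 0.4). That permutation test leaves the pairs out of account. With mean ovary marker expression as a covariate 2 of the 13 calls held, and the median went from -0.57 to 0.0047 for muscle markers, from -0.68 to -0.31 for cuticle proteins and from 0.42 to 0.22 for DNA replication and cell cycle. The medians without the covariate are of edgeR log2 fold changes and those with it of limma coefficients on log2 CPM. Part of each change can therefore come from the measure. A larger ovary share cannot be told apart from other differences that follow both the first principal component and the group. Fat body, midgut, haemocyte and testis covariates left all 13 calls, but these markers hardly differed between the groups. Their correlations with the group were -0.126, -0.105, -0.0853 and -0.183, against 0.432 for ovary markers. With the first principal component they were -0.852, -0.804, -0.912 and 0.624, against 0.922. Covariates from eye and neuron, muscle, Malpighian tubule and salivary gland markers left 1, 1, 1 and 5 calls, but these lists are among the 13 called and decide nothing. Only 3 calls held without siILP1 replicate 2, whose removal also leaves its partner unmatched, and 10 held without both replicates numbered 2. Within the numbered pairs, 10 of the 13 called lists shifted in the direction of the call in all pairs, so also in those without that library. Some of these shifts were small, such as -0.077 for cuticle proteins in pair 3 and 0.043 for ribosome biogenesis in pair 2. The lists were also called from these same libraries and share members, so the count decides nothing. Whether replicate 2 labelled siILP1 is the whole cause cannot be told, and an effect of the injected RNA stays open and untested.

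The lower stress-induced heat shock genes in the libraries labelled siILP1 may come from NC replicate 3. The median log2 fold change of the 6 genes was -4.29 with all libraries and -1.78 without that library, with 5 of 6 below 0, so that library sets much of the size and cannot be told apart as the whole cause. A general difference in chaperone mRNA is argued against by the whole list, which had a median of 0.05 over 43 genes. The other 37 members had a median of 0.1 (quartiles -0.08 and 0.25). That test adds little, because it was chosen after the values were seen and leaving out lower genes cannot lower the median. Handling before extraction, or a response to the injected RNA, was not tested.

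For genes in edgeR the real split gave 0, so that all 10 splits of the 6 libraries into 3 and 3 give as many whatever the data, and this count tests nothing; the highest other split gave 69. For lists the real split gave 13, 5 of the 10 splits gave as many, and the highest other gave 23. With 10 splits no share can be under 0.1. The split that puts both replicates numbered 2 with siILP1 replicate 1 gave the 69 genes in edgeR and 1343 in DESeq2, which points to a structure of the samples that the groups do not follow. Among the 4 splits that part all 3 pairs, the real one gave 13 lists, and the others gave 13, 8 and 1. In edgeR with the block the real split had 1435 genes at an unadjusted p under 0.05 and the others 547, 293 and 126, and without the block 365 against 198, 160 and 74. With only 4 such splits, a first rank decides nothing.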
